A study of Capra hircus with 7 samples.

How the data were processed

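RNA was measured by RNA-seq in 7 libraries of goat (Capra hircus) mammary gland cells grown in 3D culture. Per the labels, the material was total RNA, and the cells had received virus that carried cirRNA28250, a circular RNA (circRNA), or that inhibited its expression. The deposited table lists 17374 genes with 1 FPKM value per gene and library (fragments scaled to transcript length and to mapped fragments), which the authors made from their reads and rounded to hundredths, per the file headers and the values themselves. The aligner, the gene model, the genome build, the strandedness of the libraries and any scaling between libraries are not given in the sources used here. The identifiers were matched to gene symbols with a RefSeq gene table of assembly ARS1.2, used for names only; 17007 identifiers matched and 367 identifiers that carry a BGI_novel prefix did not. No coordinates are given, because the build behind the table is not named. Groups were taken from the sample titles: c3NC (2 libraries), c5NC (1 library), cKDmix (2 libraries, knockdown) and cRNA28250 (2 libraries, overexpression). The design text lists 3NC beside the knockdown and 5NC beside the overexpression, so c3NC served as the control of the knockdown and c5NC as the control of the overexpression; the labels do not spell these abbreviations out. Nothing in the labels says whether replicates came from separate cultures or animals, so the p-values measure only the spread between these libraries, which may be technical.

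FPKM values are not counts, so no count model was used. Genes with at least 1 FPKM in at least 2 of the 7 libraries were tested (12180 genes), on log2(FPKM + 1); fold changes are on that scale, which understates the change of genes with low values. All 7 libraries entered 1 limma fit (limma 3.58.1 in R 4.3.3) with 1 mean per group, which leaves 3 residual degrees of freedom, and eBayes with a trend on mean expression added 4.66 prior degrees of freedom. c5NC has 1 library and is assumed to vary like the libraries of the other groups. The contrasts were cKDmix minus c3NC, cRNA28250 minus c5NC, the difference between these effects, and c3NC minus c5NC. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The groups, contrasts, tests, 36 gene lists, the rule for the genes named and all alternatives but the 3 added later were fixed before the data were examined. Lists with at least 5 tested genes (30 of the 36) were compared with all other genes by camera, two-sided, with the correlation between genes of a list preset at 0.01 and Benjamini-Hochberg adjustment over the 30 lists of a contrast; the same test with the correlation estimated from the residuals was an alternative. With the estimated correlation, camera also tests on the 3 residual degrees of freedom, so few lists can pass whatever their correlation. Fibroblast markers in knockdown lost their call there (camera adjusted p = 0.431) at an estimated correlation of −0.0332, under the preset. A call lost there therefore cannot be laid to correlation alone. List medians are given relative to the median of all tested genes. Members of each list were counted at the threshold over all genes and again adjusted over the list alone.

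The genes named are, per direction, the 8 called genes with the largest fold change in which the libraries of the groups compared do not overlap and the higher group averages at least 2 FPKM; up to 4 members of each list that passes camera, by smallest p in the direction of the list; and, for the difference between the effects, the 6 genes with the smallest p and opposite signs and the 4 with the smallest p whatever the signs. Symbols that are only locus numbers were left out, and 3 genes that meet the rule are not reported here. Other genes are said to have been chosen after their values were seen. The circRNA itself was not analysed here, because a circRNA has to be matched by its own identifier and not by its host gene.

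The alternatives were a pseudocount of 0.1, no filter, a filter on the mean, quantile normalization, scaling by the median ratio to a geometric mean library, no variance trend, only the libraries of the groups compared, the replicate number as a block, all 3 control libraries as 1 group, the estimated correlation, and leaving out each library in turn. Using c3NC as the control of the overexpression, c5NC as the control of the knockdown, and a block with the cKDmix numbers swapped were added after seeing the data. Before use, the fit was tested on simulated data made from the mean of each gene over all 7 libraries, with independent noise. In these data 100 genes were changed by 1 and 100 by 2 on the log2 scale. All of them were drawn from genes with a mean log2(FPKM + 1) above 2, so recovery of genes with lower means was not simulated. No other difference between groups and no correlation between genes was simulated. Recovery in the real data, with 4191 genes called in knockdown, may therefore differ. For the knockdown comparison the fit recovered 51% of the genes changed by 1 and 99% of those changed by 2, with 14 false calls among 164. For the overexpression comparison it recovered 29% and 96%, with 13 false calls among 138. Remaining tables and plots were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

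Depth in reads is unknown for FPKM values, so no counting interval or detection floor is given. FPKM summed to 476096 to 642595 per library. In a library with fewer reads each read is worth more FPKM, so the most frequent ratio between low values, from 0.1 to 0.5 FPKM, was taken as a guide to depth. It tracks depth only where such values stem from the same small number of reads, which FPKM values do not show. Rounding to hundredths also favours a ratio of 1.0. Against c3NC replicate 1 that ratio was 0.933 in c3NC replicate 2, 1.23 in c5NC, 1.0 and 1.07 in cKDmix, and 0.933 and 1.0 in cRNA28250. Each ratio is the fullest bin, which held 13 to 23 of the 150 to 260 genes compared. Replicate libraries were compared before averaging: the SD of their log2 difference was 0.2998 in c3NC, 0.306 in cKDmix and 0.586 in cRNA28250, with Pearson r of 0.989, 0.986 and 0.952 across genes, which are not independent replicates. No pair held identical columns.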

Results

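Transcript levels were measured in 7 RNA-seq libraries of mammary gland cells from the Lanshan dairy goat, kept in 3D culture, in which the level of cirRNA28250 had been altered with virus. A circRNA is a closed loop of RNA made by back-splicing. The groups were cKDmix, the knockdown, with 2 libraries; c3NC, its control, with 2 libraries; cRNA28250, the overexpression, with 2 libraries; and c5NC, the control of the overexpression, with 1 library. Between 10896 and 11870 of 17374 genes reached 1 FPKM in a library, and the 10 most abundant genes held 14.3% to 20.2% of the summed FPKM. Both cKDmix libraries listed more genes at 1 FPKM or above (11701 and 11853) than both c3NC libraries (10896 and 10941), and fewer at 0 (1809 and 1758 against 2768 and 2692). The first principal component, with 48.5% of the variance, placed the cKDmix libraries at 50.03 and 57.25, the control libraries between −37.96 and −29.95, and cRNA28250 replicates 1 and 2 at −14.3 and 12.2. The second, with 19.96%, set c5NC (−52.8) apart from the other libraries (−8.42 to 21.5). Replicates of cRNA28250 differed more than those of the other groups, with an SD of the log2 difference of 0.586 against 0.2998 in c3NC and 0.306 in cKDmix.

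Genes typical of fibroblasts were abundant in every library. DCN, a small collagen-binding proteoglycan, stood at 5251 to 8882 FPKM, LUM, a related proteoglycan, at 757 to 3275, and VIM, an intermediate filament protein of mesenchymal cells, at 2758 to 7644. The epithelial genes KRT5, KRT8, KRT18 and EPCAM stayed at or below 0.53 FPKM in all 7 libraries; these 7 genes were chosen for naming after their values were seen. Of 21 luminal epithelial markers, all measured, 6 passed the filter, against 16 of 17 fibroblast markers. Of 12 milk protein genes, 6 were measured and 0 passed the filter, the highest value being 0.25 FPKM. The highest value of a luminal marker was 111 FPKM. Of 17 basal or myoepithelial markers measured, 9 passed the filter. Among these were ACTA2 (63.5 to 834 FPKM) and TAGLN (162 to 1296 FPKM), chosen after their values were seen, while KRT5 and KRT14 did not pass. Of 11 adipocyte markers measured, 5 passed. Markers of endothelium, macrophages and lymphocytes gave 2, 4 and 1 tested genes. The mitochondrially encoded list had 0 measured genes and the list of replication-dependent and linker histones 4, so neither was tested.

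The comparison of cKDmix with c3NC asks which transcripts changed when cirRNA28250 was knocked down. Called genes were mostly lower in cKDmix among immediate early genes (13 of 26 tested), ribosomal protein genes (37 of 70) and nuclear genes of the respiratory chain (9 of 30). They were higher among interferon-stimulated genes (24 of 34) and DNA replication genes (15 of 33). These 5 lists passed camera with the preset correlation and lost that call with an estimated correlation (Benjamini-Hochberg adjusted p from 0.431 to 0.729). FOS, a transcription factor induced rapidly by growth factors and stress, averaged 428 ± 86.6 FPKM in c3NC and 1.89 ± 0.113 FPKM in cKDmix (SD, n = 2 each), a log2 fold change of −7.20 ± 1.45 (SE; limma, Benjamini-Hochberg adjusted p = 0.0113). TIMP3, an inhibitor of matrix metalloproteinases, averaged 10.2 ± 3.85 FPKM in c3NC and 225 ± 3.19 FPKM in cKDmix, a log2 fold change of 4.38 ± 0.29 (limma, Benjamini-Hochberg adjusted p = 0.000381). Of 12180 genes tested, limma called 4191, of which 3270 were higher and 921 lower in cKDmix. Among these, 2225 changed at least 2-fold, 1786 upward and 439 downward. The median of all tested genes was 0.30 higher in cKDmix on the log2 scale, and quantile normalization moved it to −0.02. With that scaling 2729 genes were called, 1339 higher and 1390 lower, so that the share of higher calls went from 78.0% to 49.1%; scaling by the median ratio called 3708 genes, 57.0% of them higher. Quantile normalization and the unscaled values shared 2124 calls in the same direction.

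Among the genes with the largest rises were PCSK1N, the precursor of an inhibitor of prohormone processing, MXRA8, an adhesion protein of the cell surface, F13A1, the A subunit of coagulation factor XIII, and AARD. Log2 fold changes of the 8 such genes, which also include CCDC3, TIMP3, CRIP1 and KIAA1456, ran from 4.31 to 4.76. PCSK1N was listed at 0 and 0.06 FPKM in c3NC and at 31.9 and 22.7 FPKM in cKDmix, and MXRA8 went from 2.57 ± 1.14 to 78.8 ± 3.18 FPKM. AARD averaged 0.28 ± 0.198 FPKM in c3NC and 31.3 ± 0.113 FPKM in cKDmix. The genes with the largest falls were FOS, FOSB, TMEM65, EGR1, KCNJ8, SPINK9, KLF2 and NTRK3, with log2 fold changes from −7.20 to −3.48. KCNJ8, a pore subunit of ATP-sensitive potassium channels, fell from 77.2 ± 5.56 to 2.25 ± 0.573 FPKM, and NTRK3, a neurotrophin receptor, from 31.5 ± 0.0212 to 1.91 ± 0.099 FPKM. TMEM65, which encodes a mitochondrial inner membrane protein, averaged 956 ± 133 FPKM in c3NC and 15.6 to 32.1 FPKM in each of the other 5 libraries.

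Immediate early genes, which respond to growth factors and stress without new protein synthesis, were lower in cKDmix. Of 26 tested, 13 were lower, 1 higher and 12 not called (also 13 and 1 adjusted over the list alone). The list median was −1.35 relative to all genes (camera, Benjamini-Hochberg adjusted p = 1.06e-08). With an estimated correlation the call was lost (adjusted p = 0.652; 4.7e-14 to 0.652 over the 18 alternatives). EGR1, a zinc finger factor, fell from 109 ± 5.22 to 3.37 ± 0.651 FPKM, and JUNB from 247 ± 9.68 to 80.5 ± 8.51 FPKM. NR4A2, a nuclear receptor, had a log2 fold change of −2.14 ± 0.33, and ZFP36, which promotes mRNA decay, of −1.85 ± 0.36 (limma, Benjamini-Hochberg adjusted p = 0.00582 and 0.0102). Outside the knockdown, cRNA28250 replicate 2 was also low in these genes: FOS was at 5.15 FPKM there against 300.2 FPKM in replicate 1, and EGR1 at 8.59 against 155 FPKM.

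Cytosolic ribosomal protein genes shifted downward together in cKDmix. Of 70 tested, 37 were lower and 0 higher (45 and 0 adjusted over the list alone), with a list median of −1.38 relative to all genes (camera, Benjamini-Hochberg adjusted p = 3.95e-24). With an estimated correlation, which was 0.953, and 3 residual degrees of freedom the call was lost (camera adjusted p = 0.652, and 2.68e-29 to 0.652 over the 18 alternatives). RPLP2, a protein of the ribosomal stalk, fell from 638 ± 11.3 to 216 ± 54.0 FPKM; RPL18 and RPL8 had log2 fold changes of −1.49 ± 0.29 and −1.33 ± 0.28. Nuclear genes of oxidative phosphorylation were lower in 9 of 30 tested and higher in 0 (9 and 0 adjusted over the list alone), with a relative median of −0.88 (camera, Benjamini-Hochberg adjusted p = 5.88e-10; with an estimated correlation, adjusted p = 0.652; 1.71e-12 to 0.652 over the 18 alternatives). SDHB, the iron-sulfur subunit of succinate dehydrogenase, fell from 89.9 ± 7.55 to 45.9 ± 4.77 FPKM, and the complex I genes NDUFA6 and NDUFA9 had log2 fold changes of −1.23 and −0.79. After quantile normalization the ribosomal median relative to all genes went from −1.38 to −0.53, and 21 ribosomal protein and 8 respiratory chain genes were lower and 0 of either higher. Lists called lower in cKDmix held more abundant transcripts than those called higher. Their median FPKM in c3NC replicate 1 ran from 14.5 (inflammatory) to 1008 (ribosomal), against 4.41 (interferon) and 3.72 (DNA replication). Hypoxia (68.7) and mitosis (3.985) genes passed camera in neither direction. Whether the shifts follow abundance was not tested. Of 16 nuclear-retained transcripts, chosen after the data were seen and not tested as a list, 11 were called higher in cKDmix (median of the 16 1.32, of all genes 0.30). Ribosomal protein genes share sequence with pseudogene copies, so single values are uncertain.

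Interferon-stimulated genes rose in cKDmix: 24 of 34 tested were higher and 0 lower (26 and 0 adjusted over the list alone). The list median was 0.66 above all genes (camera, Benjamini-Hochberg adjusted p = 2.85e-06); with an estimated correlation the adjusted p was 0.431 (2.12e-07 to 0.431 over the 18 alternatives). After quantile normalization 14 were higher and 1 lower. DDX58, a sensor of viral RNA, rose from 1.95 ± 0.0707 to 14.01 ± 2.74 FPKM, and SAMD9, an antiviral factor, from 0.51 ± 0.0707 to 9.26 ± 2.93 FPKM. RSAD2, an antiviral enzyme, stood at 2.23 and 2.96 FPKM in cKDmix and at 0.06 to 0.44 FPKM in the other 5 libraries, and PARP9 had a log2 fold change of 1.62 ± 0.19 (limma, Benjamini-Hochberg adjusted p = 0.00331). Genes of DNA replication and S phase were higher in 15 of 33 tested and lower in 0 (18 and 0 adjusted over the list alone), with a relative median of 0.74 (camera, Benjamini-Hochberg adjusted p = 0.00229; with an estimated correlation, adjusted p = 0.729; 0.000192 to 0.729 over the 18 alternatives). MCM6, a helicase subunit, rose from 7.59 ± 0.0495 to 18.4 ± 1.12 FPKM. HELLS and CCNE2 had log2 fold changes of 1.45 and 1.38 and lost their calls with quantile normalization (limma, Benjamini-Hochberg adjusted p = 0.0510 and 0.0602; 0.000184 to 0.190 and 0.000196 to 0.0907 over the alternatives), which left 2 genes of the list called. Of 40 mitosis genes, 6 were higher and 1 lower, and that list did not pass camera (Benjamini-Hochberg adjusted p = 0.152).

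Inflammatory, matrix, lysosomal and glycolytic lists had medians below that of all genes in cKDmix, with members in both directions. The glycolysis list itself barely moved, with a median log2 fold change of −0.0056 against 0.30 for all genes. Of 23 inflammatory genes tested, 7 were lower and 4 higher, with a relative median of −0.64 (camera, Benjamini-Hochberg adjusted p = 0.00148; 0.431 with an estimated correlation; 0.000278 to 0.431 over the alternatives). ICAM1, a leukocyte adhesion receptor, fell from 51.7 ± 3.82 to 7.97 ± 0.12 FPKM. S100A8 and S100A9, the calgranulins, had log2 fold changes of −2.37 and −2.58, and the chemokine CCL20 of −1.96. Fibroblast markers had 5 of 16 lower and 1 higher (relative median −0.85, camera adjusted p = 0.00175; 0.431 with an estimated correlation). DPT, a matrix protein, fell from 84.2 ± 5.33 to 32.2 ± 3.90 FPKM, with PDGFRB, CXCL12 and COL1A2 at log2 fold changes of −1.16, −1.04 and −1.30. In the matrix and TGF-beta list 6 of 37 were lower and 5 higher (−0.67, camera adjusted p = 0.0063; 0.694 with an estimated correlation). MMP14, COL4A1 and FN1 had log2 fold changes of −1.79, −1.90 and −2.11. In the lysosome and autophagy list 5 of 33 were lower and 1 higher (−0.52, camera adjusted p = 0.00327; 0.466 with an estimated correlation). Among the lower were WIPI1 at −1.28, CTSL at −0.97, GABARAPL1 at −0.87 and CTSZ at −0.86. In the glycolysis list 2 of 20 were lower and 1 higher (−0.30, camera adjusted p = 0.0210; 0.694 with an estimated correlation). PFKFB3, a regulator of glycolytic flux, had a log2 fold change of −1.76 and fell from 50.4 ± 6.19 to 14.1 ± 0.898 FPKM, and ENO2, an enolase, fell from 22.0 ± 2.90 to 10.5 ± 0.82 FPKM, while PFKP (−0.57) and GAPDH (−0.80) were not called. Adjusted over the list alone, the counts of lower and higher genes were 7 and 4, 5 and 1, 2 and 5, 5 and 1, and 2 and 1 in these 5 lists. Quantile normalization ended 4 of these calls, with camera adjusted p of 0.397 for fibroblast markers, 0.490 for the lysosome list and 0.832 each for the matrix and glycolysis lists. Over all alternatives these 4 spanned 0.000335 to 0.819, 0.00135 to 0.653, 0.000335 to 0.832 and 0.0071 to 0.832. Leaving out 1 library ended the matrix call without c3NC replicate 2 (adjusted p = 0.0550) and the glycolysis call without c3NC replicate 1 (0.0717). FN1, COL1A2, COL4A1 and MMP14 lost their calls with quantile normalization (limma, Benjamini-Hochberg adjusted p from 0.056 to 0.209; 7.63e-05 to 0.864 over all alternatives of these genes).

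The other 20 lists did not pass camera in the knockdown (Benjamini-Hochberg adjusted p from 0.0582 to 0.903). Milk fat synthesis genes had 6 of 36 higher and 4 lower (6 and 4 adjusted over the list alone; adjusted p = 0.397), small RNA and circRNA machinery 9 of 24 higher and 0 lower (9 and 0; adjusted p = 0.0582), and sterol synthesis genes 8 of 20 higher and 0 lower (9 and 0; adjusted p = 0.336). The number of genes called fell to 45 without cKDmix replicate 2, 187 without cKDmix replicate 1, 384 without c3NC replicate 1 and 1260 without c3NC replicate 2. It rose to 6387 and 6394 without cRNA28250 replicates 1 and 2. Of the 52 called genes named, 11 were called in every such fit (AARD, MXRA8, CCDC3, TIMP3, F13A1, CRIP1, TMEM65, KCNJ8, NTRK3, SAMD9 and ICAM1). Against c5NC, a control chosen after seeing the data, 2655 genes were called, 1819 of them among the 4191. There TMEM65, CTSZ, COL1A2, ENO2, PFKP, DPT and the fibroblast and matrix lists turned direction. Of the 52 called genes named, 33 kept call and direction against c5NC, 14 lost their calls and 5 turned. NDUFA9, MMP14 and COL4A1 were at 24.2, 172 and 82.1 FPKM in c5NC, near their cKDmix means of 23.67, 152 and 73.3 FPKM. The inflammatory and lysosome lists lost their calls there (camera adjusted p = 0.110 and 0.653).

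**Figure D1:**
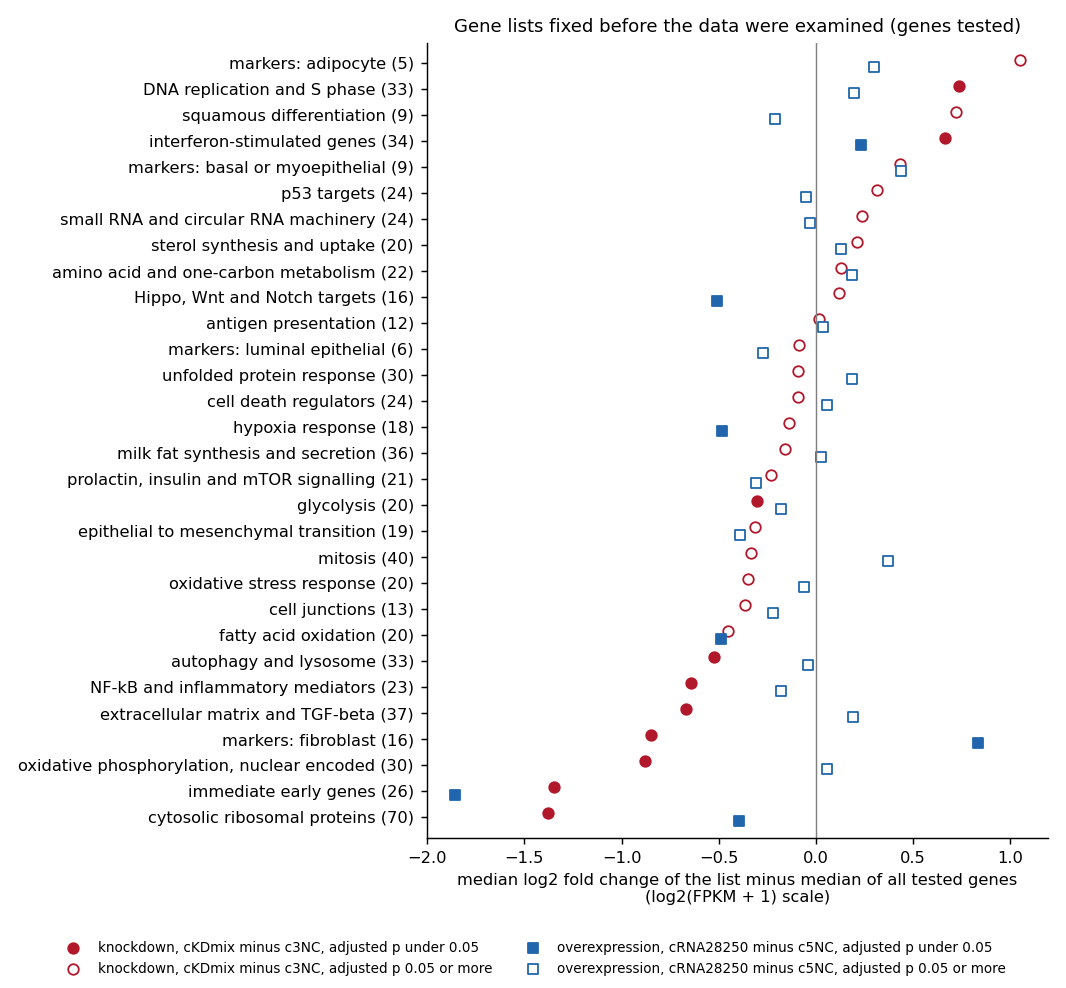
Median log2 fold change of each gene list minus the median of all tested genes, on the log2(FPKM + 1) scale, for knockdown (circles, cKDmix minus c3NC) and overexpression (squares, cRNA28250 minus c5NC); filled symbols passed camera at an adjusted p under 0.05 with the preset correlation (0 of them with an estimated correlation), and the number of tested genes stands in parentheses. Ribosomal protein genes lay at −1.38 in knockdown and −0.40 in overexpression, immediate early genes at −1.35 and −1.86, and fibroblast markers at −0.85 and 0.84, of which the knockdown value turned direction against c5NC and the overexpression value was 0.04 against c3NC.

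The comparison of cRNA28250 with c5NC asks which transcripts changed when cirRNA28250 was overexpressed. NDUFA4L2, a mitochondrial protein induced by low oxygen, stood at 1.99 FPKM in c5NC and averaged 174 ± 42.5 FPKM in cRNA28250 (SD, n = 2), a log2 fold change of 5.85 ± 0.31 (SE; limma, Benjamini-Hochberg adjusted p = 0.000353). GPX3, a secreted glutathione peroxidase, went from 4.61 to 330 ± 221 FPKM, and MXRA8, which was also higher in the knockdown, from 0.48 to 114 ± 29.5 FPKM. CLCA2, a regulator of chloride conductance in epithelium, went from 150 FPKM in c5NC to 1.495 ± 1.45 FPKM. Limma called 928 genes, 618 higher and 310 lower, and 886 of them changed at least 2-fold. The replicates of cRNA28250 differed with an SD of 0.586, against 0.2998 in c3NC and 0.306 in cKDmix. A variance estimate shared by all groups may understate that spread, so the p-values of this contrast may be too small. With only the libraries of these groups 231 were called, and with all 3 control libraries as 1 group 191. The median of all tested genes was 0.16 higher in cRNA28250; after quantile normalization it was −0.02 and 723 genes were called, 374 higher and 349 lower, so that the share of higher calls went from 66.6% to 51.7%. Scaling by the median ratio called 984 genes, 56.7% of them higher.

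The 8 largest rises were in ACTG2, a smooth muscle actin, MXRA8, LY6E, NDUFA4L2, GPX3, KLK7, a serine protease, VAT1L and ASPN, a matrix proteoglycan, with log2 fold changes from 5.11 to 6.63. The 8 largest falls were in CLCA2, HAS3, a hyaluronan synthase, C5AR1, the receptor of complement fragment C5a, PERP, a desmosomal protein, PLTP, a phospholipid transfer protein, HJURP, a centromere chaperone, GNG8 and CARD10, with log2 fold changes from −6.05 to −3.81. NDUFA4L2 and GPX3 were also low in c3NC and cKDmix (at most 2.6 and 6.97 FPKM). The fallen genes were low in c3NC too: PERP was at 225 FPKM in c5NC, at 3.38 and 12.4 FPKM in c3NC and at 8.88 and 13.97 FPKM in cRNA28250, and PLTP at 2682 FPKM in c5NC and 101 to 294 FPKM elsewhere. ACTG2 and VAT1L were at 1.64 and 0.16 FPKM in c5NC and at least 161 and 28.3 FPKM in c3NC. ASPN and LY6E were also low in c5NC (0.32 and 0.99 FPKM), against at least 4.09 and 18.47 FPKM in c3NC. In these genes both c3NC libraries stayed below both cRNA28250 libraries.

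Immediate early genes were lower in cRNA28250, with 8 of 26 lower and 2 higher (13 and 4 adjusted over the list alone) and a relative median of −1.86 (camera, Benjamini-Hochberg adjusted p = 2.03e-07; 0.756 with an estimated correlation; 2.05e-18 to 0.756 over the 17 alternatives). IER3 went from 305 FPKM in c5NC to 59.0 ± 23.5 FPKM, IER2 from 57.5 to 17.1 ± 3.91 FPKM, BTG2, an antiproliferative gene, from 135 to 45.7 ± 8.27 FPKM and ZFP36 from 480.0 to 77.1 ± 42.5 FPKM. c5NC stood apart in these genes: c3NC had IER2 at 19.9 and 16.5 FPKM and BTG2 at 44.6 and 51.0 FPKM. With c3NC as the control, chosen after seeing the data, IER2, BTG2 and ZFP36 lost their calls. The cRNA28250 replicates also differed, with FOS at 300.2 and 5.15 FPKM. Fibroblast markers were higher in 6 of 16 and lower in 0 (7 and 0 adjusted over the list alone), with a relative median of 0.84 (camera, Benjamini-Hochberg adjusted p = 0.0213; 0.756 with an estimated correlation; 6.4e-05 to 0.981 over the 17 alternatives). DPT rose from 8.12 to 101 ± 22.2 FPKM, THY1, a surface glycoprotein, from 8.36 to 112 ± 39.4 FPKM, LUM from 757 to 2961 ± 444 FPKM and FAP from 16.4 to 54.6 ± 18.9 FPKM. c5NC was the library apart here, since c3NC had DPT at 87.9 and 80.4, LUM at 2031 and 2137 and FAP at 37.4 and 38.1 FPKM, and these 3 genes lost their calls with c3NC as the control. Interferon-stimulated genes were higher in 3 of 34 and lower in 0 (also 3 and 0 over the list alone), with a relative median of 0.23 (camera adjusted p = 0.0213; 0.756 with an estimated correlation; 0.000577 to 0.756 over the alternatives): EPSTI1, XAF1 and HERC6 had log2 fold changes of 2.07, 1.58 and 1.94, while IFI6 (1.28) was not called. HERC6 was at 0.95 FPKM in c5NC, 4.8 and 5.17 FPKM in c3NC, and 8.65 and 4.8 FPKM in cRNA28250.

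Hypoxia response genes had 4 of 18 lower and 1 higher (4 and 1 adjusted over the list alone), with a relative median of −0.48 (camera, Benjamini-Hochberg adjusted p = 0.00853; 0.756 with an estimated correlation). LOX, which crosslinks collagen, went from 635 to 167 ± 3.48 FPKM and NDRG1 from 343 to 102 ± 31.0 FPKM, and PDK1 and ANGPTL4 had log2 fold changes of −1.04 and −1.15. c3NC was already near the cRNA28250 level in LOX (152 and 259 FPKM), NDRG1 (96.9 and 105 FPKM) and PDK1 (14.2 and 13.3 FPKM), and with c3NC as the control LOX and NDRG1 lost their calls and PDK1 turned direction. Fatty acid oxidation genes had 1 of 20 lower (4 adjusted over the list alone), ECI1, an enoyl-CoA isomerase (47.1 and 37.3 FPKM in c3NC, 47.1 and 36.0 FPKM in cRNA28250), at −1.19 (list median −0.49, camera adjusted p = 0.00202; 0.756 with an estimated correlation). DECR1, CPT2 and HADHA, at −0.89, −0.85 and −0.82, were not called. Targets of Hippo, Wnt and Notch signalling had 1 of 16 lower (1 over the list alone), LEF1 at −1.32 (list median −0.51, camera adjusted p = 0.00853; 0.756 with an estimated correlation), with AJUBA at −1.50, CYR61 at −1.24 and JAG1 at −0.82 not called. Ribosomal protein genes had 0 of 70 called in either direction (0 and 0 over the list alone), while the list median of −0.40 passed camera (adjusted p = 0.000602; 0.976 with an estimated correlation). RPL35, RPL36, RPLP2 and RPS10 were at −1.05, −0.92, −0.69 and −0.74. The median FPKM of the ribosomal list was 1109 in c5NC, 731 in cRNA28250 replicate 1 and 1319 in replicate 2, so the replicates lay on either side of c5NC. Over the 17 alternatives the adjusted p of these 4 lists ran from 0.00222 to 0.756, 0.00156 to 0.756, 0.00111 to 0.756 and 1.36e-12 to 0.976. Quantile normalization ended the ribosomal, hypoxia and interferon calls (adjusted p = 0.211, 0.0849 and 0.0849), and leaving out cRNA28250 replicate 1 ended the ribosomal (0.726), Hippo (0.104), interferon (0.135) and fibroblast (0.313) calls.

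The other 23 lists did not pass camera in the overexpression (Benjamini-Hochberg adjusted p from 0.110 to 0.967), among them milk fat synthesis, with 6 of 36 higher and 2 lower (11 and 3 adjusted over the list alone; adjusted p = 0.729). Without 1 library, 308 genes were called (without either cKDmix library), 493 and 497 (without c3NC replicates 1 and 2), and 2904 and 1954 (without cRNA28250 replicates 1 and 2). Among the 33 called genes named, 21 were called in every such fit. The fits without 1 library could not leave out c5NC, the only control library here, so they do not test how far the genes rest on it. With c3NC as the control, chosen after seeing the data, 525 genes were called and 239 of them were among the 928. MXRA8, LY6E, NDUFA4L2, GPX3, KLK7, ANGPTL4, IER3, EPSTI1, XAF1 and THY1 kept call and direction. CLCA2, C5AR1, PERP, CARD10, LEF1 and PDK1 turned direction. The fatty acid oxidation, Hippo and fibroblast lists lost their calls (adjusted p = 0.509, 0.203 and 0.509), and 17 more named genes lost theirs.

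**Figure D2:**
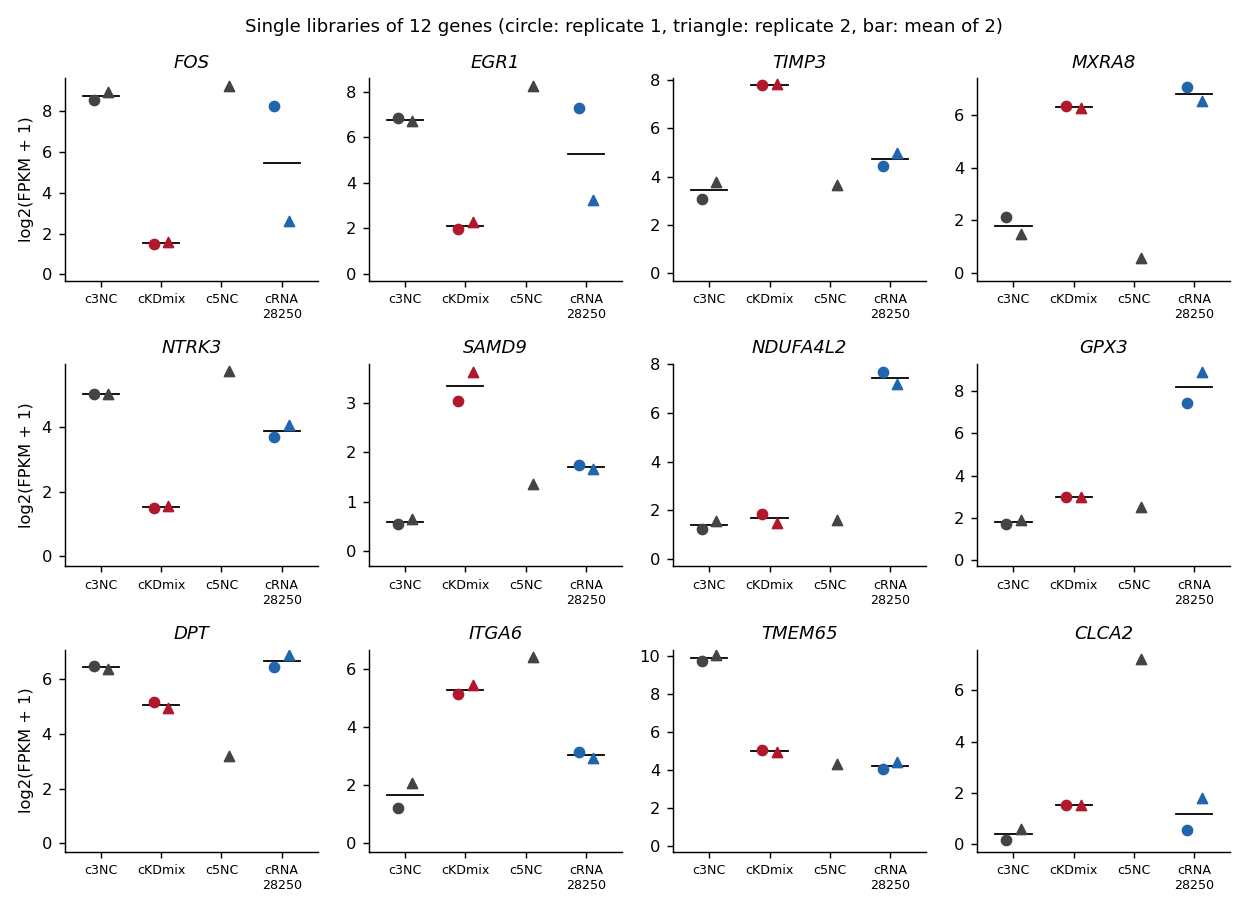
Level of 12 genes in each library as log2(FPKM + 1), with replicate 1 as circles, replicate 2 as triangles and the mean of 2 libraries as a bar; c5NC has 1 library. FOS is low in both cKDmix libraries (1.81 and 1.97 FPKM) and in cRNA28250 replicate 2 (5.15 FPKM), TMEM65 is high only in c3NC, CLCA2 only in c5NC, and NDUFA4L2 and GPX3 only in cRNA28250.

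A gene that follows the level of cirRNA28250 would move in opposite directions in the 2 modifications. The difference between the effects tests whether they are unequal, not whether they are opposite. ITGA6, an integrin subunit of epithelial basement membrane contacts, averaged 2.27 ± 1.33 FPKM in c3NC and 38.3 ± 5.71 FPKM in cKDmix, and went from 84.5 FPKM in c5NC to 7.22 ± 0.891 FPKM in cRNA28250, a difference between the effects of −7.03 ± 0.46 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.00065). AARD and SLC40A1, the iron exporter ferroportin, rose in knockdown (4.66 and 4.08) and were at −1.46 and −1.66 in overexpression, both near 0 FPKM in c3NC and cRNA28250. GPX7, a peroxidase of the endoplasmic reticulum, and REM1, a small GTPase, were lower in knockdown (REM1 −1.89) and at 3.34 each in overexpression. GPX7 averaged 16.8 FPKM in c3NC, 3.36 FPKM in cKDmix and 18.7 FPKM in cRNA28250, against 0.94 FPKM in c5NC. REM1 averaged 7, 1.165 and 9.715 FPKM in these groups, against 0.06 FPKM in c5NC. HS3ST6, a heparan sulfate sulfotransferase, was at 1.86 and −2.99. It was at 11.8 FPKM in c5NC and averaged 0.165 FPKM in c3NC and 0.615 FPKM in cRNA28250. In GPX7, REM1 and HS3ST6 cRNA28250 was thus near c3NC, and c5NC was the library apart. ITGA6 in cRNA28250 was also far nearer to c3NC than to c5NC. It lay above c3NC there, which is the direction of its knockdown change. AARD and SLC40A1 were at 1.84 and 2.56 FPKM in c5NC, so their lower values in overexpression rest largely on that library. Of 12180 genes, 938 differed between the effects, 449 with a higher and 489 with a lower overexpression effect. Of these, 765 had opposite signs and 171 were called in both comparisons with opposite signs. A test of the difference favours genes with opposite signs, so the number 765 is partly built in. Among all 427 genes called in both comparisons, 256 had the same direction. Both controls take part in this difference, so its overlap with the genes called between c3NC and c5NC (419 of the 938) is partly built in.

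Effects of knockdown and overexpression were weakly related across genes (Pearson r = 0.175, Spearman rho = 0.228, where genes are not independent replicates). No library enters the group means of both comparisons, but both were tested with the same variance estimate per gene, from the same fit. Genes with a small variance are therefore more readily called in both, in either direction, and the numbers for independent lists below ignore this. Of the 427 genes called in both, 256 had the same direction: 209 were higher in both, where independent lists would share 166. Another 47 were lower in both, where they would share 23.4. A further 88 were higher in knockdown and lower in overexpression (83.2 for independent lists) and 83 the reverse (46.7). With quantile normalization those 4 overlaps were 91, 73, 54 and 78, where independent lists would share 41.1, 39.8, 38.4 and 42.7. With and without that scaling all 4 exceeded these numbers, opposite directions included, so their excess cannot be laid to shared effects alone.

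Between the effects, 8 lists differed by camera with the preset correlation and 0 with an estimated one (Benjamini-Hochberg adjusted p from 0.370 to 0.904 for these 8). Relative medians, overexpression effect minus knockdown effect, were 0.96 for ribosomal protein genes (adjusted p = 2.79e-08, 0 of 70 called), 0.91 for oxidative phosphorylation (4e-07, 2 of 30 higher), 2.03 for fibroblast markers (4.4e-06, 6 of 16 higher). They were −0.65 for interferon-stimulated genes (0.0134, 4 of 34 lower and 1 higher), 0.80 for mitosis genes (0.0256, 0 of 40 called), 0.38 for lysosome genes (0.0325, 1 of 33 higher), 0.41 for inflammatory genes (0.0325, 5 of 23 higher and 1 lower) and 0.81 for matrix genes (0.0490, 3 of 37 higher and 3 lower). Adjusted over the list alone, the called members were 0, 2, 9, 14, 0, 0, 10 and 6 in these lists. Immediate early genes, lower in both comparisons, did not differ as a list by this test (camera adjusted p = 0.864). Members went both ways, with 3 of 26 higher and 4 lower (5 and 5 adjusted over the list alone). The other 21 lists had camera adjusted p of 0.148 to 0.864. Quantile normalization ended the mitosis, lysosome, inflammatory and matrix calls (0.0632, 0.265, 0.107 and 0.663), and leaving out cRNA28250 replicate 1 did the same (0.976, 0.0860, 0.202 and 0.402). Without c3NC replicate 2 or cKDmix replicate 1 the mitosis (0.349 and 0.0614) and matrix (0.153 and 0.146) calls were lost. The count of 938 genes fell to 93 and 145 without cKDmix replicates 2 and 1 and to 229 and 320 without c3NC replicates 1 and 2. It rose to 2441 and 3430 without cRNA28250 replicates 1 and 2. All 6 genes named were called in each of these fits. These fits could not leave out c5NC, the only control library of the overexpression, so they do not test how far the 6 genes rest on it. With all 3 control libraries as 1 group, AARD and SLC40A1 kept their calls, and ITGA6 (−2.25), HS3ST6 (−1.39), GPX7 (2.17) and REM1 (2.31) lost theirs.

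**Figure D3:**
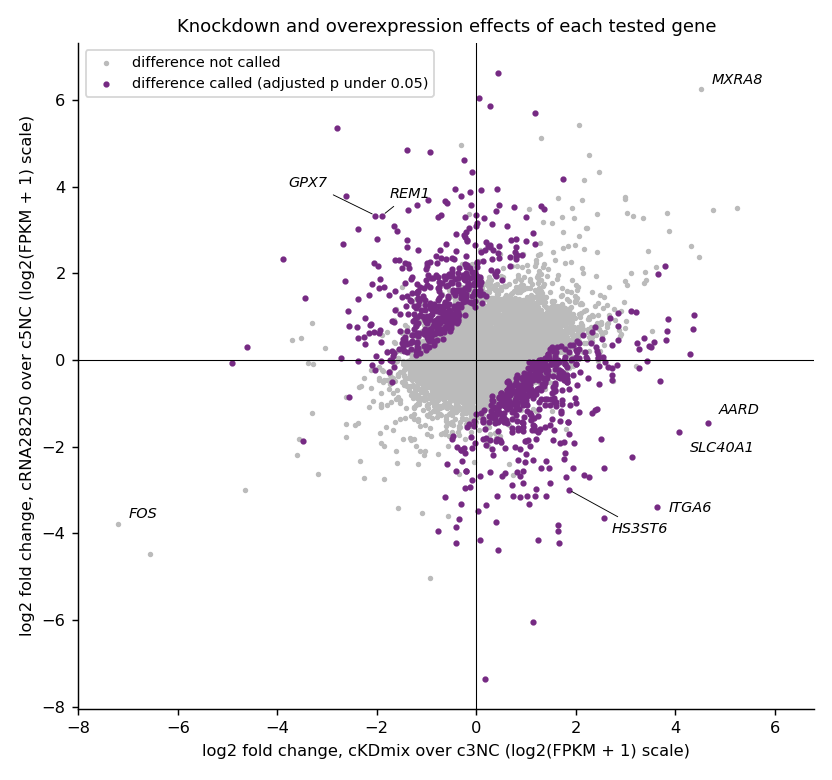
Log2 fold change of each of 12180 tested genes in knockdown (x axis, cKDmix over c3NC) and overexpression (y axis, cRNA28250 over c5NC), on the log2(FPKM + 1) scale, with the 938 genes whose effects differed in purple. MXRA8 lies high in both comparisons at 4.52 and 6.25. ITGA6 lies at 3.64 and −3.38, with 84.5 FPKM in c5NC against means of 2.27 FPKM in c3NC and 7.22 FPKM in cRNA28250. FOS lies at −7.20 and −3.77, the latter not called and low in cRNA28250 replicate 2 alone.

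The controls were compared with each other as the background of these contrasts. Limma called 707 genes between c3NC and c5NC (2250 at an unadjusted p under 0.05), 333 higher and 374 lower in c3NC, and 690 changed at least 2-fold. ACTG2 (log2 difference 6.05 ± 0.44), TMEM65 (5.59 ± 0.26) and TGFBI, a matrix protein induced by TGF-beta (5.18 ± 0.45), were higher in c3NC, and CLCA2 (−6.85 ± 0.47), DIO3, which inactivates thyroid hormone (−6.80 ± 0.61), and EHF, an epithelial transcription factor (−5.14 ± 0.23), were higher in c5NC; these genes were chosen after their values were seen. Of the 928 genes called in overexpression, 433 were also called between the controls, and of the 4191 called in knockdown, 323; each pair of contrasts shares a control, so some overlap is built in. The count was 192 and 219 without c3NC replicates 1 and 2, 204 without either cKDmix library, and 1879 without either cRNA28250 library; c5NC has no replicate.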

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

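The tests of handling, the knockdown as the sole reason, 1 scaling factor per library, a larger nuclear share, depth, epithelial cells and the circRNA, and the use of c3NC as the other control, were chosen only after the result was seen.

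Knockdown and overexpression effects differed in 938 genes by a test of the difference itself (limma, Benjamini-Hochberg adjusted p under 0.05 over 12180 genes). The same test over lists singled out 8, given as the median of the overexpression effect minus the knockdown effect, relative to all genes. The values were 0.959 for ribosomal protein genes, 0.908 for oxidative phosphorylation, 2.03 for fibroblast markers and −0.653 for interferon-stimulated genes. They were 0.802 for mitosis genes, 0.385 for lysosome and autophagy genes, 0.405 for inflammatory genes and 0.813 for matrix and TGF-beta genes. With an estimated correlation camera called 0 of these 8. Of the 938 genes, 419 also differed between c3NC and c5NC, an overlap partly built in, since both controls enter the difference.

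Immediate early genes were lower in both cKDmix libraries, with a median fall of −2.14 over the 13 genes called lower. The knockdown as the sole reason is left undecided by 1 library: 11 of these 13 genes were nearer to the cKDmix mean than to the c3NC mean in cRNA28250 replicate 2, where 1 was in replicate 1. The 2 cRNA28250 libraries, which share a treatment, differed in these genes by a median of −1.43, against 0.12 over all genes. Handling at harvest, unrelated to the circRNA, is therefore a candidate explanation, since FOS and EGR1 respond to stress and fresh medium. A contribution of the knockdown stays open, because both cKDmix libraries were low and both c3NC libraries high.

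Ribosomal protein and respiratory chain genes were lower in cKDmix, where more genes reached 1 FPKM than in c3NC (10896 and 10941). More genes than in c3NC also did so in c5NC (11045) and in cRNA28250 replicates 1 and 2 (11479 and 11870). Against 1 scaling factor per library, the median of the ribosomal protein genes, not set against all genes, was −1.08 unscaled, −1.36 after median ratio scaling, which applies such a factor, and −0.55 after quantile normalization, which does not. A larger nuclear share of the RNA cannot be told apart from other reasons: in cRNA28250 replicate 2 ribosomal protein genes (0.859 above replicate 1) were higher together with nuclear transcripts (1.08), but that is 1 library, and the nuclear transcripts were listed after others of their kind had been seen to be higher. Greater depth of the cKDmix libraries is left undecided. The most frequent ratio of low values over c3NC replicate 1 was 1.0 and 1.07, in bins of 23 and 15 genes. That ratio compares depths only if the values stem from the same small number of reads, which FPKM values do not show. A change in ribosomal protein mRNA through the knockdown stays open as a hypothesis, as do RNA integrity and library preparation, which were not tested.

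Genes such as CLCA2, EHF and PKP1 were high in c5NC and low in the other libraries. Between the controls 707 genes were called, with 1 library of c5NC, and whether the level of the circRNA differs between them cannot be told apart from other reasons, since that level was not analysed here. Epithelial cells with the usual keratins are argued against by KRT5, KRT8, KRT18 and EPCAM, picked after their values were seen, at most 0.53 FPKM in c5NC against PERP at 225 FPKM, but KRT19 (5.53), KRT14 (4.22), KRT7 (3.81), DSP (26.5), CLDN1 (62.6) and LAMA3 (13.2 FPKM) were highest in c5NC. Cells with part of an epithelial program, a different control construct, a different culture and a mislabelled sample stay open, and with 1 library of c5NC none of them was tested. Falls in cRNA28250 of genes high in c5NC may therefore belong to c5NC, and CLCA2 was at 0.80 in log2 fold change with c3NC as the control.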

How the results depend on the processing

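Using c3NC or c5NC as the other control and swapping the cKDmix numbers were chosen after seeing the data; the other alternatives were not. Where a value below moved and no reason is given, the cause was not tested. Over alternatives that keep all libraries, named genes kept direction and side of the threshold in 898 values, lost a call in 112, gained one in 6 and turned in 17; lists kept it in 200, lost it in 53 and turned in 6. Without 1 library, genes kept it in 494, lost it in 168 and gained it in 16, and lists kept it in 146 and lost it in 14; a lone library was assumed to vary like the other groups. The number of reads is unknown for FPKM values, which limits what can be said of genes near 0.

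Quantile normalization called 2729 genes in knockdown instead of 4191, turned the matrix list in knockdown by the direction camera gives (its median, −0.13, kept its sign), and left 4 lists in overexpression and 4 between the effects; median ratio scaling left 5 between the effects. With an estimated correlation, where camera tests on 3 residual degrees of freedom, 0, 0 and 0 lists were called in knockdown, overexpression and the difference. With only the groups compared, 6390 genes were called in knockdown, 231 in overexpression and 1325 between the controls. With the replicate block, 615 genes differed between the effects and 443 between the controls, while knockdown and overexpression gave 4084 and 672, and the fibroblast list in overexpression (adjusted p = 0.118; 6.4e-05 to 0.981 over its alternatives) and the mitosis (0.0526; 1.32e-09 to 0.976) and matrix (0.123; 1.04e-05 to 0.904) lists between the effects lost their calls; swapping the cKDmix numbers gave 1178 between the effects.

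With all 3 control libraries as 1 group, 191 genes were called in overexpression and 465 between the effects; DECR1 (0.78), JAG1 (0.11), the fibroblast list in overexpression (median 0.41) and the matrix list between the effects (0.0288) turned, the lists by camera alone, since their medians kept their sign. With c3NC as control, 525 genes were called in overexpression, and CLCA2 (0.80), C5AR1 (0.86), PERP (0.67), CARD10 (0.81), DECR1 (1.61), CPT2 (0.13), LEF1 (0.47), JAG1 (0.57), PDK1 (0.25) turned, as did the fibroblast list by camera alone (median 0.0394, sign kept). With c5NC as control, 2655 genes were called in knockdown, and TMEM65 (0.69), CTSZ (0.31), COL1A2 (0.25), ENO2 (0.58), PFKP (0.0809), DPT (1.86) and the fibroblast (0.31) and matrix (0.13) lists turned.

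Without 1 library the calls ran from 45 (without cKDmix replicate 2) to 6394 (without cRNA28250 replicate 2) in knockdown, from 308 (without either cKDmix library) to 2904 (without cRNA28250 replicate 1) in overexpression, from 93 (without cKDmix replicate 2) to 3430 (without cRNA28250 replicate 2) between the effects, and from 192 (without c3NC replicate 1) to 1879 (without either cRNA28250 library) between the controls. Lists called ran from 9 to 12, 6 to 12 and 6 to 12. Without a cRNA28250 library the replicates of that group, which spread most, no longer enter the variance.

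A pseudocount of 0.1, no filter, a filter on the mean and no variance trend kept the 4 counts of genes within 1.5 times: 3048 to 4243 in knockdown, 791 to 1044 in overexpression, 668 to 978 between the effects and 587 to 845 between the controls. Among these settings, no filter lost 11 of the 52 called genes named in knockdown and 8 of the 33 in overexpression. It ended the Hippo (adjusted p = 0.240; 0.00111 to 0.756 over its alternatives) and fibroblast (0.119; 6.4e-05 to 0.981) list calls in overexpression, and the mitosis (0.0575; 1.32e-09 to 0.976) and matrix (0.245; 1.04e-05 to 0.904) calls between the effects.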

Other observations

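The genes named here were chosen after their values were seen. Of 16 transcripts known to be partly retained in the nucleus, listed after others of their kind had been seen to be higher, 11 were called higher in cKDmix, among them PNISR (log2 fold change 2.26), TTC14 (2.33), CLK1 (1.79) and ZRANB2 (1.91; limma, Benjamini-Hochberg adjusted p = 0.0143, 0.00507, 0.0119 and 0.0072). The p53 targets MDM2 (1.96), ZMAT3 (1.91) and FAS (1.46) were higher in cKDmix, in a list that did not pass camera. PPARG, a regulator of adipocyte and milk fat genes, was at 40.1 FPKM in c5NC, 0.50 and 0.39 FPKM in c3NC, 3.97 and 4.12 FPKM in cKDmix, and 3.75 and 7.57 FPKM in cRNA28250.

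Some genes reached 5 FPKM in every library of 1 group and stayed under 0.5 FPKM elsewhere. NDN (24.8 and 20.2 FPKM) and RAB44 (12.8 and 11.7 FPKM) did so in cRNA28250, and CD53 (10.03 and 9.16 FPKM) and B3GNT9 (10.95 and 9.0 FPKM) in cKDmix. In c5NC, with 1 library, 10 genes did, among them SOX9 at 10.6 FPKM, and in c3NC 0 did; no test was run on these counts.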
